A study of Mus musculus with 6 samples.

How the data were processed

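RNA-seq profiles of the tibialis anterior (TA), a fast muscle at the front of the lower leg, were compared between 3 samples of young and 3 of aged C57BL/6 mice, aged 3 and 18 months. Total RNA had been extracted with TRIzol and made into Illumina libraries, per the labels' protocols. The sex of the animals, the strandedness of the libraries and the hour of collection are not given in the sources used here. The labels name 6 separate samples, and nothing in them says whether each came from its own animal. The p-values therefore measure the spread between these samples.

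The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library), with a separate table for each library. Per the submitters' processing notes, bcl2fastq 2.19, TopHat and DESeq2 were used and the genome build was mm9. The positions in the deposited tables follow GRCm38 instead. Of the 11239 gene identifiers, 11210 are in the GENCODE M21 annotation of GRCm38, 89.0% with the same start base and 98.9% with a start within 5000 bases. Coordinates are given on GRCm38, as the deposited tables list them. The annotation holds 55536 genes, so the tables cover a subset. The rule that chose it is not given in the sources used here, and 64 of the genes are at 0 in all 6 libraries. Counts of changed genes describe this subset and not the transcriptome. Of the genes listed, 9528 are protein-coding. A single line of each table was not used here. For 14 genes whose symbols had turned into calendar dates, the symbol was restored from the gene identifier.

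The FPKM values returned whole fragment counts. With a library total and a whole transcript length per gene, 100% of the values came out within 0.001 of a whole number. The library totals found this way were 99108144, 71984420 and 102135094 fragments in young replicates 1, 2 and 3, and 101057913, 90755261 and 89919530 in aged replicates 1, 2 and 3. The listed genes held between 80.0% and 81.1% of each total. Of 2185 detected genes with a single annotated transcript, 86.3% had a recovered length equal to the annotated one. The recovery was tested on simulated data, where it returned 6 of 6 totals and exact counts for 99.0% of 5620 genes. At these depths 3 fragments of a transcript of 1 kb correspond to between 0.0294 and 0.0417 FPKM. In a chi-square test of the recovered counts, each pair of replicates in a group differed beyond sampling noise, by 29.8 to 76.3 per degree of freedom, so no library was counted as a copy of another. This does not show that the samples came from separate animals.

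Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 7690 in all. The values were taken as log2(FPKM + 1), as deposited and without further scaling, and compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a trend, two-sided). Fold changes are aged minus young on this scale, which understates the change of genes with low values. Ratios of mean FPKM are given separately as folds. Adjusted p-values are from limma with the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. In a simulation of the comparison of aged with young muscle on 7670 genes, 14% of genes changed 1.25-fold were called, 94% of those changed 1.5-fold, and 100% of those changed 2-fold or 4-fold. Among the unchanged genes of the simulation 13 were called. Every simulated gene had the same assumed spread between samples, not estimated from these data, so the shares do not hold for genes that varied more.

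Before the data were examined, 30 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Lists with at least 5 tested genes, 28 of them, were tested with limma's camera at a preset correlation of 0.01, which compares a list with the other genes tested. The tests were repeated with camera at a correlation estimated for each list, and with fry, which asks whether a list moves on balance one way. The rule names 13 genes tied to the study's topic, and up to 10 higher and 10 lower genes with the largest log2 change, leaving out predicted gene models, whose 3 aged libraries all lay on one side of the 3 young ones. In each list it names up to 4 called genes with the largest log2 change, of which some are given, not always the first by size. Those left out include genes whose calls were lost in some settings. Some genes that the rule names are not reported here. Of the 13 genes tied to the topic, Csf3 and Cdkn1a were not analysed here. The genes Pax7, Myf5, Csf3r and Cdkn2a, lay under 1 FPKM on average, and their tests come from the same model without the minimum.

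Both groups carry the same replicate numbers. After subtraction of the group means, libraries with the same number correlated across genes at 0.177, 0.182 and 0.136, and those with other numbers at -0.192 to 0.0358. The numbers may pair the samples, but subtracting the group means makes some correlations positive and others negative whatever the numbers share. These weak correlations are the only ground for such a pairing, as the labels do not say what a number shares. The main fit was fixed without a block, so its p-values do not use the pairing. A fit with the replicate number as a block called 2123 genes higher and 2001 lower.

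The alternatives fixed in advance were a pseudocount of 0.1, no minimum, a minimum of 5 FPKM, median-of-ratios scaling, quantile normalization, rescaling without the 20 genes with the highest mean, empirical Bayes without a trend or with robust estimation, array weights, the replicate block, each library left out in turn, and a change of at least 1.5-fold. Added after seeing the data were limma's voom on the recovered fragment counts and an adjustment over all 55536 annotated genes, which allows for the selection of the genes listed. How reads shared by similar genes were counted is not given in the sources used here. Values of Igkc, Ighm, Amy1, H2-Q6, H2-K1, Hba-a1, Hbb-bs, Lyz1, Mt1, the ribosomal protein genes and Gapdh, which have close relatives or pseudogenes, are uncertain for this reason. Nr1d1 and Thra overlap on opposite strands, and if the libraries are not stranded, fragments of the overlap could count for either. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.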

Results

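RNA of the tibialis anterior muscle was sequenced in 3 samples of young mice, aged 3 months, and 3 samples of aged mice, aged 18 months. Library totals lay between 71984420 and 102135094 fragments. The 6 libraries separated by age along the first principal component, which held 78.0% of the variance, and the next held 7.70%. Correlations of log2 values lay between 0.993 and 0.996 within a group and between 0.962 and 0.975 across groups.

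The comparison asked how the transcripts of this muscle differ with age, in a study concerned with G-CSF from muscle, metabolism and the loss of muscle stem cells. Aged muscle had less mRNA of the collagen genes Col1a1, Col1a2 and Col3a1, of the tendon gene Tnmd and of Myh2, the gene of the type 2A myosin heavy chain, than young muscle. Col1a1, a chain of type I collagen, was 19.4-fold lower (631 ± 166 FPKM in young and 32.6 ± 4.07 in aged, SD, n = 3 each), and Myh2 was 4.37-fold lower. Higher in aged muscle were the small GTPase gene Rasd2, 19.2-fold, and the secreted peptide gene Ostn, 10.9-fold. Of the tested genes of oxidative phosphorylation 33 of 42 fell, and of those of ribosomal proteins 30 of 42 rose, with adjusted p = 0.520 and adjusted p = 0.666 for these lists with an estimated correlation. Of the 7690 genes tested, 51.8% passed at an adjusted p under 0.05 (limma). Counts of changed genes within a list are to be read against that share. In all, 2097 genes were higher and 1885 lower. This balance depends on the scaling, with 1940 higher and 2058 lower under median-of-ratios scaling and 2648 and 1580 on rescaling without the 20 highest genes. The 3 aged libraries lay on one side of the 3 young ones for 62.8% of the genes, against 10% by chance. That 10% holds for genes not chosen by their difference with age, and how the listed genes were chosen is not given. With a change of at least 1.5-fold as well, 400 genes were higher and 575 lower, and adjusted over all annotated genes, 983 and 903.

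**Figure D1:**
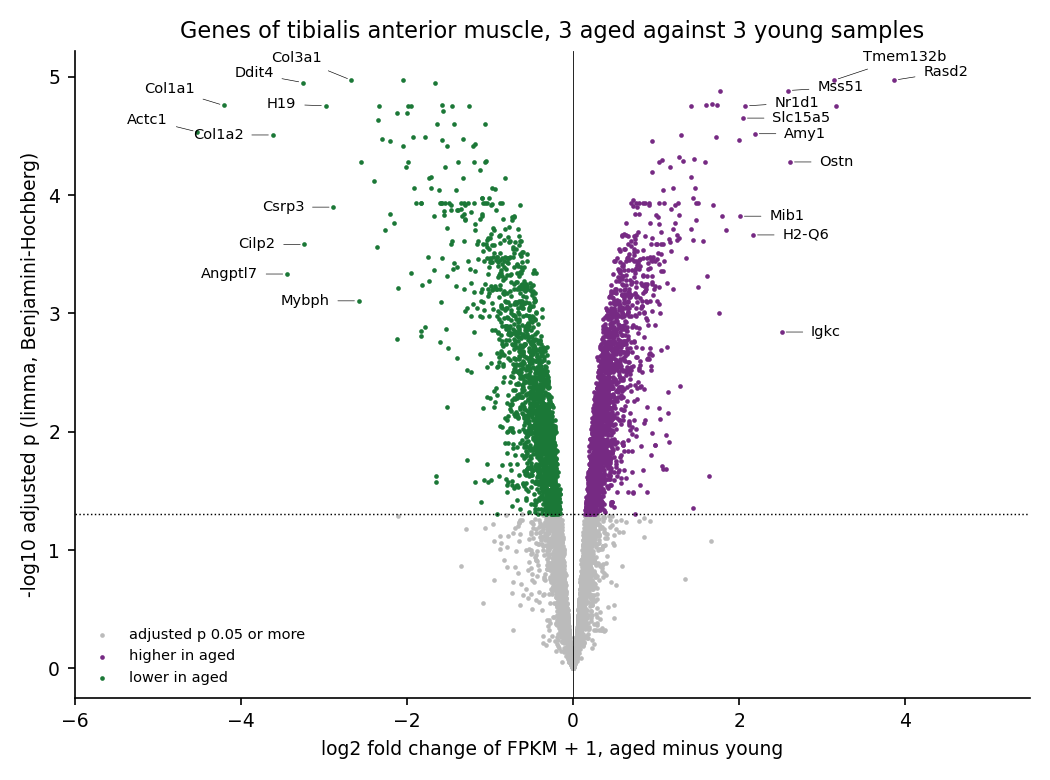
Each point is 1 of the 7690 genes tested, with its log2 fold change of FPKM + 1 (aged minus young) on the horizontal axis and the −log10 of its adjusted p (limma) on the vertical axis. Purple points are the 2097 genes higher and green points the 1885 genes lower in aged muscle at an adjusted p under 0.05 (dotted line), and the 20 named genes with the largest changes are labelled.

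Rasd2 (chromosome 8, 75213944 to 75224113) had the largest log2 rise among the named genes, 3.87 ± 0.13 (SE, adjusted p = 1.07e-05), from 2.88 ± 0.644 to 55.2 ± 5.34 FPKM (SD, n = 3). Tmem132b, a transmembrane protein gene, rose by 3.15 from 0.254 ± 0.0801 to 10.2 ± 1.56 FPKM. Ostn (chromosome 16, 27307489 to 27351212), which encodes the muscle-secreted peptide osteocrin, rose by 2.62 ± 0.17 (adjusted p = 5.24e-05). Mss51, whose product locates to muscle mitochondria (chromosome 14, 20482864 to 20496901), rose from 7.47 ± 1.10 to 49.9 ± 4.60 FPKM. The other named rises were those of Igkc, an immunoglobulin light chain gene (2.52), Amy1, an amylase gene (4.91-fold), H2-Q6, a class I histocompatibility gene (2.17), Nr1d1, a nuclear receptor of the clock (2.08), the transporter gene Slc15a5 (2.05) and the ubiquitin ligase gene Mib1 (2.01). Amy1, H2-Q6 and Igkc have close relatives that could share their reads, and Nr1d1 overlaps Thra on the opposite strand.

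Actc1, the cardiac alpha-actin gene (chromosome 2, 114047282 to 114053548), had the largest fall, −4.53 ± 0.25 (SE, adjusted p = 2.92e-05), from 628 ± 222 to 25.2 ± 3.69 FPKM. Ddit4, whose product restrains mTORC1 signalling (chromosome 10, 59949675 to 59951770), fell from 124 ± 10.7 to 12.2 ± 2.17 FPKM. H19, an imprinted noncoding RNA (chromosome 7, 142575529 to 142578143), fell from 737 ± 166 to 91.3 ± 7.60 FPKM. Csrp3, which encodes the muscle LIM protein, changed by −2.89 and Mybph, a myosin-binding protein gene, by −2.58. The other named falls were of matrix and tendon genes, namely Col1a1 (−4.20), Col1a2 (−3.62), Angptl7 (−3.44), Cilp2 (−3.23) and Col3a1 (−2.67). Of the 123 named genes that passed, 96 also passed adjusted over all annotated genes and 108 passed in each fit with 1 library left out.

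The genes tied to the study's topic moved in different directions. Myh2, Myh1 and Myh4 lie side by side on chromosome 11, and each encodes the myosin heavy chain of a fibre type. Myh2, of type 2A fibres (67171027 to 67197517), fell from 899 ± 126 to 206 ± 18.9 FPKM (log2 change −2.12 ± 0.11, adjusted p = 2.01e-05). Myh1, of type 2X fibres (67200052 to 67224575), fell from 3571 ± 184 to 2243 ± 299 FPKM. Myh4, of type 2B fibres (67238029 to 67260446), rose from 6070 ± 451 to 8457 ± 169 FPKM (0.48 ± 0.07, adjusted p = 0.00141). Myh7, of slow fibres (chromosome 14, 54970688 to 54994634), was at 0.676 ± 0.167 FPKM in young muscle and at 7.83, 6.67 and 1.07 in aged replicates 1, 2 and 3 (log2 change 1.64 ± 0.48, adjusted p = 0.0235). Its call was lost without young replicate 2 (adjusted p = 0.0601), young replicate 3 (0.0624), aged replicate 1 (0.0619) or aged replicate 2 (0.0749), with robust estimation (0.0699), with voom on the recovered counts (0.0531) and over all annotated genes (0.169).

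Among the regulators, Myod1, a myogenic transcription factor gene (chromosome 7, 46376474 to 46379099), rose from 7.43 ± 0.608 to 14.1 ± 3.22 FPKM (0.82 ± 0.15, adjusted p = 0.00411). Esrra, the gene of the estrogen-related receptor alpha (chromosome 19, 6910977 to 6921813), fell from 254 ± 2.01 to 208 ± 16.1 FPKM (−0.29 ± 0.07, adjusted p = 0.00861, and 0.0622 over all annotated genes). Ppargc1a, the gene of its coactivator PGC-1 alpha (chromosome 5, 51454250 to 51567726), changed from 14.9 ± 2.50 to 11.5 ± 0.389 FPKM (−0.33 ± 0.11, adjusted p = 0.0315). That call was lost without young replicate 3 (0.0571, with a change of −0.21), aged replicate 1 (0.0730), 2 (0.0698) or 3 (0.0553), without the minimum of 1 FPKM (0.0525), on rescaling without the 20 highest genes (0.0651), and over all annotated genes (0.228). Pax7, the transcription factor of muscle stem cells (chromosome 4, 139737062 to 139833528), stood at 0.847, 1.12 and 1.01 FPKM in young and 0.601, 0.535 and 0.599 in aged muscle, from 1015 and 618 fragments in all. Without the minimum of 1 FPKM its log2 change was −0.33 ± 0.06 (adjusted p = 0.00820). Csf3r, the G-CSF receptor gene (chromosome 4, 126024550 to 126044440), stood at 0.127 ± 0.0998 FPKM in young and 0.457 ± 0.194 in aged muscle, from 78 and 267 fragments (0.37 ± 0.11, adjusted p = 0.0389 without the minimum). Myf5, with 450 and 364 fragments, did not pass there (adjusted p = 0.313), nor did Cdkn2a, with 7 and 25 (adjusted p = 0.111).

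Contractile genes moved both ways. Of 14 tested genes of the fast fibre list, 4 rose, 4 fell and 6 did not pass, with 8 changed when adjusted over the list alone. Casq1, the calcium buffer of the sarcoplasmic reticulum, fell from 1683 ± 96.1 to 1156 ± 102 FPKM, while Myh4 rose. Of 14 genes of the slow fibre list, 5 rose, 5 fell and 4 did not pass, with 10 changed when adjusted over the list alone. Those that fell were led by Csrp3, by Ankrd2, a stretch-responsive gene (327 ± 42.7 to 65.3 ± 21.7 FPKM), and by Myoz2, a calcineurin-binding Z-disc gene (82.3 ± 11.3 to 19.9 ± 0.970 FPKM). Neither list passed camera (adjusted p = 0.746 for fast and 0.789 for slow). The medians of the fast list (0.0017) and the slow list (0.13) were above 0, while their means and tests pointed down. The slow genes that rose were Myh7 and, named after their values were seen, Tnni1 (3.08-fold, adjusted p = 0.0106), Tnnc1 (2.89-fold, 0.0206), Myl2 (2.52-fold, 0.0122) and Tnnt1 (2.34-fold, 0.00782). These genes were lower in aged replicate 3 than in the other aged libraries, with Tnnc1 at 3.28 and Tnni1 at 2.47 FPKM there. The Tnnc1 call was lost without young replicate 2 (adjusted p = 0.0582), young replicate 3 (0.0592) or aged replicate 2 (0.0649), and over all annotated genes none of them passed (0.0565 to 0.169).

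**Figure D2:**
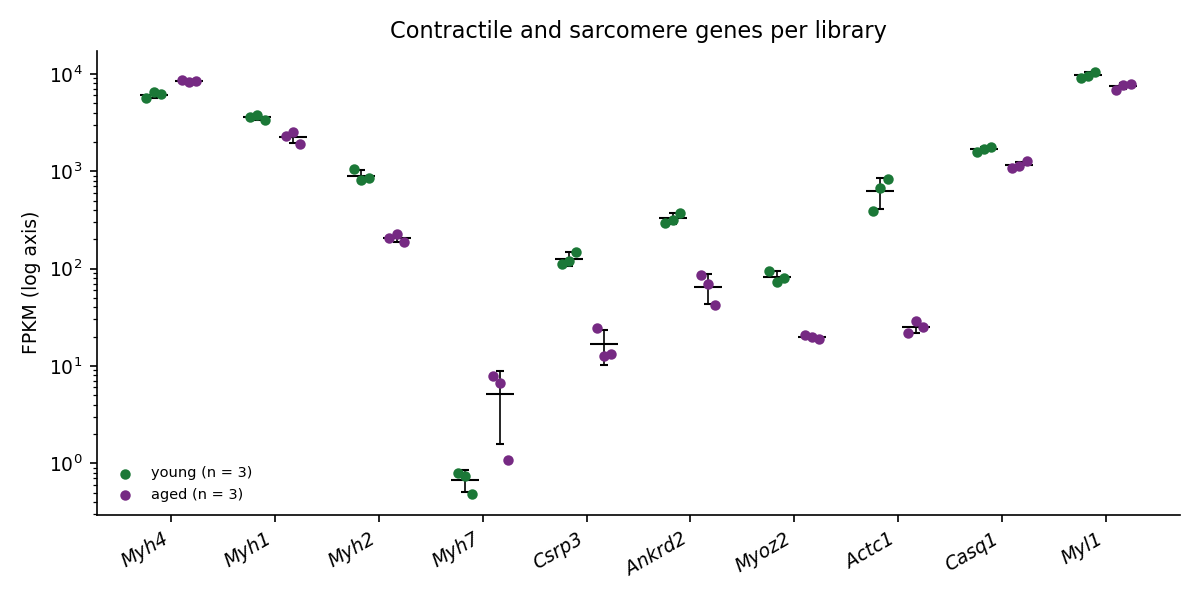
FPKM (log axis) of 10 contractile and sarcomere genes in each library, with points for the 3 young (green) and 3 aged (purple) libraries and bars for the mean and SD. Myh2 lies near 899 FPKM in young and 206 in aged muscle, Myh4 is higher in aged muscle, and Myh7 spreads from 1.07 to 7.83 FPKM among the aged libraries.

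Of 42 tested genes of oxidative phosphorylation, 33 fell, 0 rose and 9 did not pass, with a median log2 change of −0.25 (36 changed when adjusted over the list alone). Cox7a1, a subunit of cytochrome c oxidase, fell from 816 ± 53.7 to 575 ± 37.7 FPKM, and Atp5g3, of the ATP synthase, from 737 ± 30.3 to 535 ± 31.9. The list passed camera (adjusted p = 3.30e-07), with an adjusted p = 0.520 with an estimated correlation. Of 16 genes of the tricarboxylic acid cycle, 12 fell, 1 rose and 3 did not pass (14 changed when adjusted over the list alone; camera adjusted p = 0.00148, and 0.520 with an estimated correlation). Dlat and Pdha1, both of the pyruvate dehydrogenase complex, changed by −0.61 ± 0.06 and −0.48 ± 0.05.

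Of 28 genes of glycolysis and glycogen, 13 fell, 4 rose and 11 did not pass (19 changed when adjusted over the list alone). Pfkfb3, which makes an activator of glycolysis, rose from 30.5 ± 5.91 to 99.1 ± 6.72 FPKM, and Fbp2, a gluconeogenic phosphatase gene, from 29.0 ± 3.85 to 55.4 ± 8.24. Gbe1, the glycogen branching enzyme gene, fell from 63.3 ± 4.30 to 37.0 ± 3.74 FPKM. The list passed camera downwards (adjusted p = 0.0256), with an adjusted p = 0.520 with an estimated correlation. That call was lost without young replicate 3 (adjusted p = 0.0889) and with quantile normalization (0.209). Gapdh, named after its values were seen, stood at 67.3 FPKM in aged replicate 3 and between 557 and 736 in the other libraries. Fatty acid oxidation did not pass (29 genes, 9 lower and 4 higher, 13 changed when adjusted over the list alone, adjusted p = 0.265). Acot2, a mitochondrial thioesterase gene, rose by 1.14 ± 0.24 and Ppara, a lipid-sensing receptor gene, changed by −0.64 ± 0.06. Of 15 genes of estrogen-related receptors and PGC-1, 4 rose and 4 fell (8 changed when adjusted over the list alone, adjusted p = 0.789), with Esrrb at 0.58 ± 0.08 and Sirt3 at −0.38 ± 0.08.

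Tendon and matrix genes had the lowest median changes of the 28 lists tested. Of 36 extracellular matrix genes, 32 fell, 0 rose and 4 did not pass, with a median log2 change of −0.93 and 32 changed when adjusted over the list alone. Col3a1, of type III collagen (chromosome 1, 45311538 to 45349706), fell from 239 ± 10.5 to 37.0 ± 4.69 FPKM, and Sparc, a collagen-binding glycoprotein gene, from 618 ± 123 to 104 ± 17.5. Tendon genes fell with them, 13 of 15 with 0 higher (median −1.83, 13 changed when adjusted over the list alone). Tnmd, a marker of tendon cells, fell from 13.9 ± 4.54 to 2.03 ± 0.273 FPKM and Cilp2 from 14.3 ± 6.61 to 0.519 ± 0.227. Scx, a tendon transcription factor gene inside an intron of Bop1, was at 0.04 on the log2 scale and did not pass. Of 17 markers of fibro-adipogenic progenitors, the fibroblast-like cells between the fibres, 13 fell and 0 rose (median −0.52, 15 changed when adjusted over the list alone), among them Mfap5 (18.7 ± 2.42 to 7.40 ± 1.45 FPKM) and Igfbp6 (48.4 ± 8.12 to 27.8 ± 5.33). Camera gave adjusted p = 1.31e-13 for matrix, 3.04e-06 for tendon and 0.00127 for progenitor markers, and adjusted p = 0.520 for each with an estimated correlation.

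**Figure D3:**
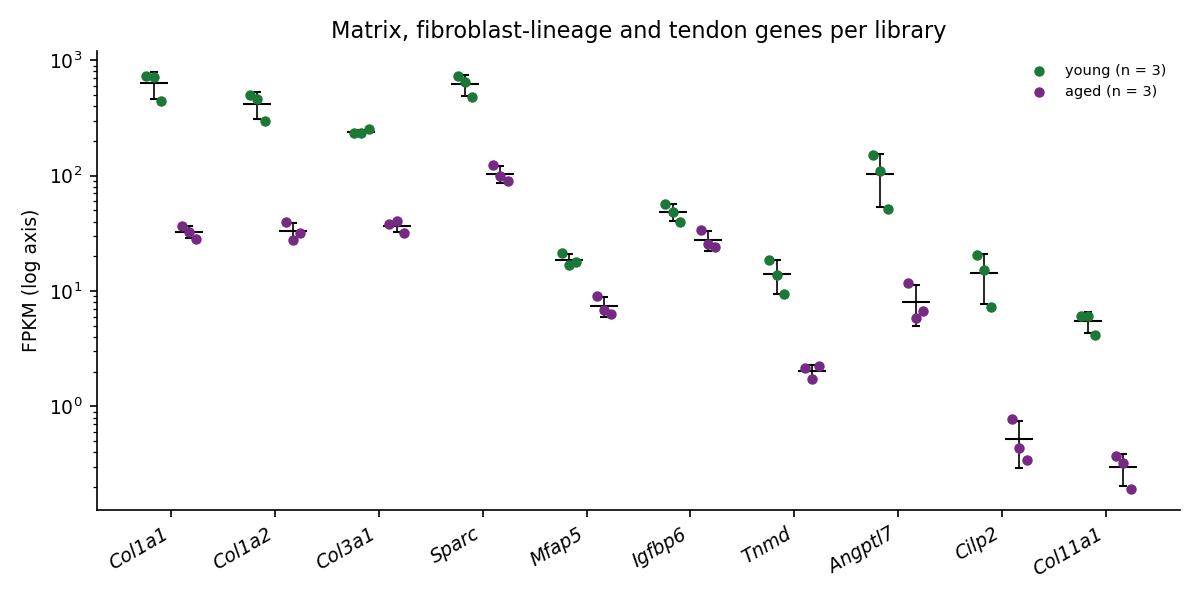
FPKM (log axis) of 10 matrix, fibroblast-lineage and tendon genes in each library, with points for the 3 young (green) and 3 aged (purple) libraries and bars for the mean and SD. In each gene the 3 aged libraries lie below the 3 young ones, from 37.0 against 239 FPKM on average for Col3a1 to 0.519 against 14.3 for Cilp2.

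Of 21 endothelial genes, 11 fell and 2 rose (13 changed when adjusted over the list alone). Sox17, an arterial transcription factor gene, fell from 25.4 ± 2.86 to 12.5 ± 1.82 FPKM, and Kdr, the gene of a VEGF receptor, rose from 8.50 ± 0.816 to 15.9 ± 3.76. Camera gave adjusted p = 0.0231, adjusted p = 0.0703 without aged replicate 3, and adjusted p = 0.677 with an estimated correlation. Of 11 Schwann cell and nerve genes, 6 fell and 0 rose (6 changed when adjusted over the list alone), including the myelin gene Pmp22 (−0.65 ± 0.06). Their adjusted p = 0.0177 became 0.0552 without young replicate 2 and adjusted p = 0.550 with an estimated correlation. Smooth muscle and pericyte genes did not pass (6 of 15 lower and 1 higher, 7 changed when adjusted over the list alone, adjusted p = 0.180), nor did adipocyte genes (7 of 16 lower and 3 higher, 10 changed when adjusted over the list alone, adjusted p = 0.180), though the adipocyte list passed with a minimum of 5 FPKM (0.0311) and fry (0.00752). In these, Pdgfrb, a pericyte receptor gene, changed by −0.55 ± 0.10 and Dgat2, of triglyceride synthesis, by −1.71 ± 0.12.

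Of 18 macrophage genes, 8 fell and 0 rose (8 changed when adjusted over the list alone; camera adjusted p = 0.00148, and 0.666 with an estimated correlation). The list did not pass fry (adjusted p = 0.116). Lyz1, a lysozyme gene, was at 13.1, 2.43 and 3.15 FPKM in young replicates 1, 2 and 3 and at 1.53, 0.488 and 0.739 in aged muscle (log2 change −1.65 ± 0.49, adjusted p = 0.0238). Without young replicate 1 the log2 fold change of Lyz1 was −1.01 (adjusted p = 0.0128). Its call was lost without aged replicate 2 (0.0717) or 3 (0.0673), with robust estimation (0.0706) and over all annotated genes (0.172). C1qa, a complement gene of macrophages (−0.78 ± 0.24), lost its call without young replicate 1 (0.0731), aged replicate 2 (0.0785) or aged replicate 3 (0.0736). Mrc1, the mannose receptor gene (−0.79 ± 0.25), lost it without any 1 library but aged replicate 1 (0.0582 to 0.0929), with a change of −0.51 without aged replicate 2. C1qa and Mrc1 also lost theirs without the minimum (0.0527 and 0.0615), with robust estimation (0.0561 and 0.0578) and over all annotated genes (0.193 and 0.233). Lyve1, a marker of resident macrophages, fell from 4.40 ± 0.818 to 1.85 ± 0.753 FPKM. Of 4 lymphocyte genes above the minimum, too few for a list test, the immunoglobulin genes Igkc and Ighm rose (2 changed when adjusted over the list alone), Ighm from 9.65 ± 1.63 to 29.6 ± 7.16 FPKM. Of 4 neutrophil genes, 0 passed, also when adjusted over the list alone. S100a8 was at 12.4 FPKM in aged replicate 3 and at 0.764 or less in the other libraries. S100a9, at 0.863 and 0.726 FPKM in aged replicates 1 and 2, was at 1.66 ± 0.72 on the log2 scale (adjusted p = 0.0838, 0.0294 with the replicate block, 0.0228 with a pseudocount of 0.1 and 0.0494 with voom). Without aged replicate 3 its change was 0.67 (adjusted p = 0.00819), and it also passed without aged replicate 1 (0.0496) or 2 (0.0479). Of 15 interferon response genes, 9 rose and 0 fell (9 changed when adjusted over the list alone), with Igtp, an interferon-inducible GTPase gene, at 1.04 ± 0.09 and H2-K1 at 0.64 ± 0.06. Camera gave adjusted p = 0.0404 and adjusted p = 0.520 with an estimated correlation. The interferon call was lost without young replicate 2 (adjusted p = 0.0601), in the fit with the replicate block (0.0529), and on rescaling without the 20 highest genes (0.0595). Complement genes did not pass (4 of 13 lower and 3 higher, 7 changed when adjusted over the list alone, adjusted p = 0.272), with Cfd at −0.64 ± 0.15 (adjusted p = 0.0713 over all annotated genes). C4b, at 0.94 ± 0.25, lost its call without young replicate 2 (adjusted p = 0.0517) and over all annotated genes (0.114). Of 5 erythroid genes, 3 rose (4 changed when adjusted over the list alone), the haemoglobin gene Hbb-bs from 82.9 ± 20.3 to 136 ± 4.70 FPKM. That list had adjusted p = 0.0641, 0.0452 with the replicate block and 0.00434 without young replicate 3.

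Muscle stem cell genes did not pass as a list, with 7 of 16 lower, 2 higher and 9 changed when adjusted over the list alone (adjusted p = 0.0625). The list passed fry (adjusted p = 0.00669), and its adjusted p was 0.0149 without the minimum, 0.0420 with the replicate block, 0.0449 without young replicate 1 and 0.0446 without aged replicate 2. Chodl, a marker of these cells, fell from 8.12 ± 1.15 to 3.50 ± 0.568 FPKM, and Myod1 rose. Of 19 genes of the neuromuscular junction and denervation, 6 fell and 3 rose (9 changed when adjusted over the list alone, adjusted p = 0.409). Sln, which inhibits the calcium pump, rose by 1.04 ± 0.22, Hdac9 by 1.04 ± 0.11, and Dok7, which activates the junction's receptor kinase, changed by −0.67 ± 0.07. Of 25 genes of atrophy and proteolysis, 12 fell and 2 rose (14 changed when adjusted over the list alone; camera adjusted p = 0.00330, and 0.520 with an estimated correlation). The largest falls in it were of Ddit4, of the transcription factor genes Cebpd (54.2 ± 11.4 to 10.9 ± 2.29 FPKM) and Cebpb (86.8 ± 12.7 to 28.6 ± 5.84), and of the metallothionein gene Mt1, none of which is a protease or a ubiquitin ligase.

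Immediate early genes, which respond within minutes to stimuli, fell in 10 of 21 with 0 higher (10 changed when adjusted over the list alone; camera adjusted p = 0.00554, and 0.520 with an estimated correlation). Btg2 changed by −1.10 ± 0.14 and Klf6 by −0.70 ± 0.06. Ribosomal protein genes rose in 30 of 42 with 0 lower (median 0.33, 32 changed when adjusted over the list alone; camera adjusted p = 4.03e-05, and 0.666 with an estimated correlation). Rps25 rose from 183 ± 16.5 to 264 ± 29.6 FPKM. Of 18 clock genes, 6 rose and 4 fell (12 changed when adjusted over the list alone, adjusted p = 0.354), with Nr1d1 from 17.5 ± 1.90 to 77.1 ± 8.78 FPKM and Bhlhe40, a clock repressor gene, from 26.0 ± 1.76 to 64.9 ± 9.17. Of 29 genes of heat shock and the unfolded protein response, 8 rose and 4 fell (12 changed when adjusted over the list alone, adjusted p = 0.354), and the small heat shock gene Hspb7 fell from 317 ± 21.9 to 116 ± 25.8 FPKM. Of 9 cell cycle genes, 3 rose and 2 fell (5 changed when adjusted over the list alone, adjusted p = 0.746), with the mitotic kinase gene Aurka at 1.45 ± 0.14 and Rrm2 at −0.78 ± 0.13.

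Of 5 genes of senescence and its secretions, 3 fell, among them Mmp13, a collagenase gene (log2 change −1.82 ± 0.21), and Igfbp3, and 0 rose (3 changed when adjusted over the list alone, adjusted p = 0.180, and 9.97e-05 with fry). Of 16 factors secreted by muscle, 10 fell and 4 rose (15 changed when adjusted over the list alone, adjusted p = 0.132, and 0.0153 with fry). Besides Ostn, the signalling gene Wnt4 rose from 3.05 ± 0.220 to 8.72 ± 1.52 FPKM, and Nmb, the neuromedin B gene, fell from 6.82 ± 0.677 to 2.01 ± 0.380. Of the 28 lists tested, 2 passed camera upwards and 11 downwards, 0 passed with an estimated correlation, and 14 passed fry, the endothelial (adjusted p = 0.0927) and ribosomal protein lists (0.0660) not among them.

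**Figure D4:**
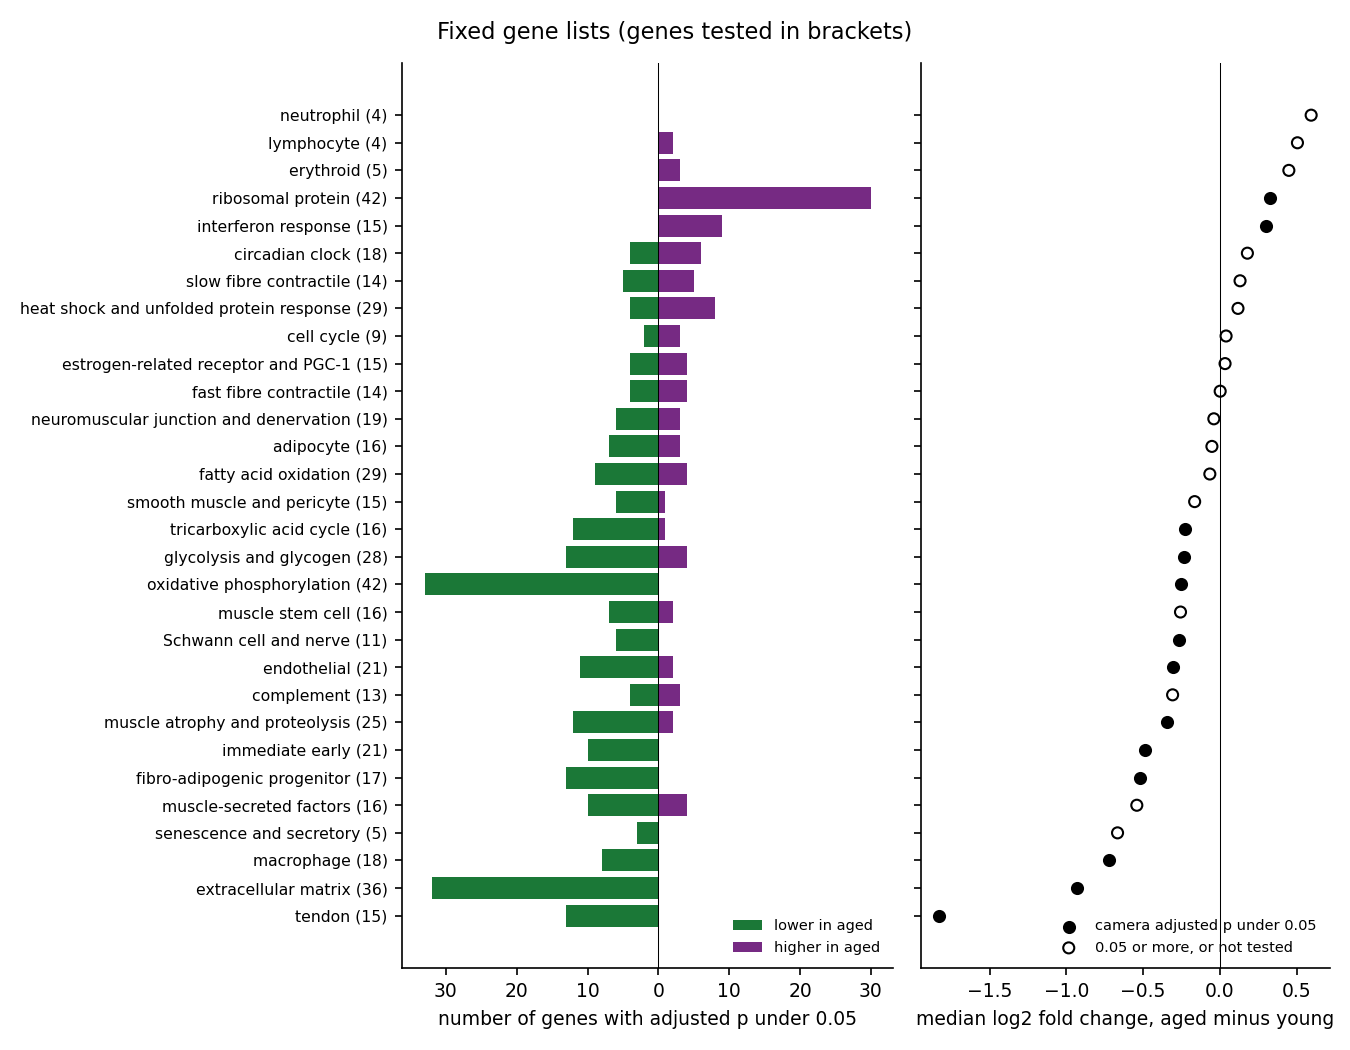
The 30 gene lists, with the number of tested genes in brackets, ordered by median log2 fold change. Bars on the left count the members higher (purple) and lower (green) in aged muscle at an adjusted p under 0.05, and points on the right give each list's median, filled where camera passed at a preset correlation, from −1.83 for tendon to 0.59 for neutrophil genes.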

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

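The voom fit on the recovered fragment counts and the adjustment over all annotated genes were chosen after seeing the data. With another pseudocount, minimum, scaling, variance model, the replicate block or voom, 1573 to 2648 genes were higher and 1266 to 2182 lower, and 12 to 14 lists passed. With 1 library left out, 1540 to 2088 genes were higher and 1431 to 1831 lower, and 11 to 14 lists passed. Of the 3982 genes called, 2981 to 3551 were called again in these 6 fits, each with the same sign. The counts moved further in 3 settings. A change of at least 1.5-fold left 400 higher and 575 lower, since it adds a criterion, and the adjustment over all 55536 annotated genes left 983 higher and 903 lower, since it counts more tests. Camera with a correlation estimated for each list called 0 lists, against 13 at the preset value and 14 with fry, and the lowest adjusted p was 0.520; the cause was not tested, though the estimated correlations reached 0.864, in the macrophage list. Rescaling without the 20 highest genes raised the share of calls that were higher from 52.7% to 62.6%, with a shift of 0.0598 in the median log2 change. Median-of-ratios scaling moved it the other way, to 48.5%, with 1940 higher and 2058 lower, so the larger direction turned.

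With the replicate number as a block, 2123 genes were higher, 2001 lower and 14 lists passed. The block ended the calls of the interferon list (adjusted p = 0.0529) and of Cspg4, a pericyte gene (0.0580), and added the muscle stem cell and erythroid lists and S100a9. It changed no other call of a named gene or list. Over all settings the named genes gave 2224 comparisons, of which 2105 kept their side of the threshold, 113 no longer passed, 6 newly passed and 0 changed direction. The lists gave 523, of which 489 kept their side, 23 no longer passed and 11 newly passed. A further 4 list comparisons, which passed under neither setting, had another sign than the main result. In the simulation of aged against young muscle 94% of genes changed 1.5-fold were called and 14% of those with the smallest change simulated. The simulation gave every gene the same assumed spread, so it does not hold for genes that varied more between samples. Among these, Retnla was 7.77-fold lower (limma adjusted p = 0.0519) and Ciart 2.37-fold higher (limma adjusted p = 0.0533) without passing.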

Other observations

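All tests in this part were chosen after the result they bear on was seen, and so were the genes first named here. Among imprinted genes, which are read from the copy of a single parent in some tissues or in all, the noncoding RNA Rian fell beside H19, 6.53-fold and its neighbour Meg3 5.52-fold (log2 change −2.21, adjusted p = 3.47e-05). The zinc finger gene Peg3 changed by −1.35, the growth factor gene Igf2 by −0.49, the cell cycle inhibitor gene Cdkn1c by −0.62 and the adaptor gene Grb10 by −0.66. Of 14 tested genes of a network of imprinted growth genes, H19 and Rian left out, 8 fell (Meg3, Peg3, Igf2, Cdkn1c and Grb10 among them), 1 (Asb4) rose and 5 did not pass. Camera gave p = 0.00503 for these 14 genes and p = 0.0406 with an estimated correlation, of −0.027. Both are unadjusted p-values of a single set and cannot be set beside the adjusted ones of the fixed lists. As the network was recalled after values of some members had been seen, they do not decide whether the network fell as a whole. Impact (0.59), Peg13 (0.93), Airn (0.47), Snrpn (0.32) and Ube3a (0.36), imprinted genes outside it, rose. Whether each of these genes is read from a single copy in muscle was not tested.

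Other large changes were of genes outside the lists or of list members under the minimum of 1 FPKM. Eda2r, the gene of a receptor of the tumour necrosis factor family, rose 3.35-fold (adjusted p = 1.75e-05). Tfrc, the transferrin receptor gene of iron uptake, fell 3.97-fold, Glul, the glutamine synthetase gene, fell 3.10-fold, and Ctsk, a collagen-degrading protease gene, fell 4.16-fold. Retnla was at 137 FPKM in young replicate 1 and at 18.2 or less in the other libraries. Without young replicate 1 its log2 change was −1.09 (limma adjusted p = 0.0334), against −2.11 with all libraries. It also passed without young replicate 2 (limma adjusted p = 0.0334), but not with any other library left out. Ltf, Ngp and Camp, genes of neutrophil granules, were at 5.45, 3.90 and 2.10 FPKM in aged replicate 3 and at 0.216 or less in the other libraries. These genes belong to the neutrophil list but lay under 1 FPKM on average, so its counts leave them out.

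Among the 10 splits of the 6 libraries into 3 and 3, the real one called 3982 genes and the highest of the others 0, and 1 split reached the real count. So few splits cannot give a share under 0.05. Each other split also mixes young and aged libraries in both of its groups, so differences with age widen the spread there and lower its calls. The counts of the other splits are therefore no measure of what chance alone would give. At an unadjusted p under 0.05 limma called 4530 genes in the real split and 33 to 143 in the others. The 3 other splits that part all 3 pairs of replicate numbers called 0 genes, with 42, 45 and 49 at an unadjusted p under 0.05.

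The fall of matrix genes came with a fall of tendon genes, whose level differed among the young libraries. If tendon tissue carried into the young samples were the whole cause, the excess of matrix genes over aged muscle would shrink between young replicates 1 and 3 as that of tendon genes did, to a median of 35.6% (95% bootstrap interval over genes 29.4 to 49.5%). It stayed at 99.8% (92.1 to 216%) for the 6 basement membrane genes tested, such as Col4a1 and Nid1, and at 76.0% (62.5 to 84.0%) for 26 other matrix genes. Between these young libraries this argues against carry-over as the whole cause and leaves it open as a part for genes such as Col1a1. The intervals cover the spread over genes, which are not independent, and not the spread between samples. The comparison of young libraries rests on replicates 1 and 3 alone. A smaller share of fibro-adipogenic progenitors as the whole cause is also argued against, as far as their markers track these cells. Matrix genes fell by 0.73 ± 0.09 (SE, log2) more than those markers. For fibroblast-lineage cells as a whole this cannot decide, as tendon genes outside the matrix list changed by −1.69 ± 0.24 (SE, log2), against −1.22 ± 0.09 for the matrix genes. Tendon carry-over for the tendon genes themselves and a lower matrix synthesis per cell with age stay open and untested.

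The Gapdh value of aged replicate 3, 67.3 FPKM, came from 5721 fragments, against 47539 to 71090 in the other libraries. A fall of glycolytic transcripts in that library is argued against by the 27 other genes of the list, whose median log2 ratio to aged replicates 1 and 2 was −0.026 (quartiles −0.18 and 0.09), against −3.29 for Gapdh. Fragments counted for near-identical copies are argued against for the 50 copies in the tables, which gained −6.98% of the missing fragments, that is, lost some; copies not analysed here stay open. A decimal place lost in the deposited value could not be told apart from a real value, as 10 times it is 673 FPKM, within the range of the other libraries, but 1 value cannot decide. No biological explanation was tested for this single library.

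Clock genes spread widely among the aged libraries, with Dbp at 72.7, 19.2 and 31.9 FPKM in replicates 1, 2 and 3 against 27.6 to 32.6 in young muscle. Collection of the aged samples at different clock phases may account for this, as 12 of 13 other genes moved between aged replicates 1 and 2 as their phase set predicts (9 near the phase of Dbp and 4 opposite to it; exact binomial p = 0.00342, though these genes are not independent). The exception was Nr1d1, at 69.8 and 86.9 FPKM, whose rise of 2.08 with age was 1.80 ± 0.10 (SE, log2) larger than that of the overlapping gene Thra, which argues against a constant share of Thra reads as its whole cause. A difference in collection time between the groups cannot be told apart from an effect of age as the cause of the Nr1d1 rise, as Nr1d1 did not follow the 9 other genes near that phase within the aged group, so that their mean change of −0.25 ± 0.33 (SE), with Per1 at −0.87 and Usp2 at −0.79 and 0 genes higher past the threshold, decides nothing for it. An effect of age on Nr1d1 and Thra transcripts that reach further into it stay open and untested.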
